A study of Homo sapiens with 16 samples.

How the data were processed

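Chromatin immunoprecipitation followed by sequencing was carried out in human primary epidermal keratinocytes treated with the LSD1 inhibitor GSK-LSD1 or with its solvent, DMSO. The labels describe 16 libraries. They comprise 12 immunoprecipitates, 2 for each combination of 3 antibodies (LSD1, H3K4me1 and H3K4me2) and 2 treatments, and 4 input libraries. The labels give the inhibitor as 2 mM for 2 days, added at 0 and 24 h; the unit is printed as written there, and since this compound is usually used at micromolar concentrations, a micro sign may have been lost from it. Groups were assigned from the labels alone.

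The 12 immunoprecipitates were represented by 6 deposited peak lists, each of which the authors made from both libraries of a group together, per the file headers. No per-library values and no input files were analysed here. No value therefore has a replicate error, and no test between treatments was possible; the labels do not say whether the libraries of a group came from separate cultures. Each treatment was called against its own pair of inputs, which the H3K4me1 and H3K4me2 lists of a treatment share.

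Bowtie2 2.1.0, SAMtools 1.1, HOMER 4.6 and 4.9.1, MACS2 2.1.1.20160309 and the genome build hg19 are named in the submitters' processing notes. LSD1 peaks were called by HOMER with a fixed peak size of 125 bp for DMSO and 129 bp for GSK-LSD1, per the file headers. A peak had to pass a false discovery rate of 0.001, a 4-fold excess over input, a 4-fold excess over the surrounding 10000 bp and a Poisson p-value of 0.0001 for both, per the file headers. The tag signal of an LSD1 peak is the authors' number of tags per 10000000 tags of the pooled libraries. The deposited findPeaks score is the caller's own tag tally at the peak, and the deposited fold values are ratios of tags over input and over the surrounding sequence. Marks were called by MACS2 in its broad mode with q-value cutoffs of 0.05 for strong and 0.1 for weak regions, per the file headers. The larger data set was scaled to the smaller one, and 1 tag was kept at each position, per the file headers. The deposited pileup is a mean fragment coverage over the region, and the deposited fold enrichment is the ratio of that coverage to the background expected from the input. The deposited −log10 of the p-value and of the q-value are means over a broad region. All these values per peak are the authors', and they were used only to describe, rank or filter peaks within a list.

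Depth was read from the file headers. The pooled LSD1 libraries held 75013348 tags with DMSO and 87850490 with GSK-LSD1. After removal of duplicates the H3K4me1 libraries held 93252419 and 104539233 tags, the H3K4me2 libraries 104211119 and 92823820, and the inputs 47812608 and 49438205, with DMSO and GSK-LSD1 respectively. A more deeply sequenced list can hold more weak peaks, and a list called against a deeper input can do so too.

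Peaks on chromosomes 1 to 22, X and Y were kept, which left every peak in the lists. Coordinates are those of hg19, counted from 1 as deposited. A peak was called shared when it overlapped a peak of the other treatment's list by at least 1 bp, and otherwise found only with that treatment. Shares of peaks carry 95% Wilson intervals. These cover counting error only, since tags and neighbouring peaks are not independent, and they hold no variation between cultures. The interval of a ratio of gained to lost sites was converted from the Wilson interval of the gained share.

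Overlap of LSD1 peaks with the marks was set against 1000 circular shifts, in which all LSD1 peaks of a chromosome were moved by the same random distance. Peaks of a mark found only with GSK-LSD1 were compared with 10000 random draws of GSK-LSD1 peaks, matched in 20 classes of width by 20 classes of the authors' fold enrichment, for their share within 1 kb of a DMSO LSD1 peak. For the marks together, overlapping peaks of all 4 mark lists were merged into regions. The number of regions found only with 1 treatment for both marks was then set beside the product of the separate counts divided by the number of regions that hold both marks. These are descriptions of the lists, not tests between treatments.

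Peaks given with coordinates follow a rule. It takes, for each antibody, the 8 strongest peaks found only with each treatment and the 5 strongest of each list, by normalised tags for LSD1 and by fold enrichment for the marks. These are 66 different peaks, 10 of which both parts of the rule take. The text gives some of them in full and summarises the others; 2 peaks on sex chromosomes are left out. An annotation of hg19 was not used here, so regions are given by coordinate without genes. For the same reason the gene lists and the named genes of the original plan were not analysed here.

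The shares, the comparisons with shifts and draws, the rule for peaks and the alternatives on overlap, thresholds, merging and list size were chosen before the data were examined. Chosen after seeing the data were the clusters of LSD1 peaks (5 or more peaks, each within 100 kb of the next), the longest stretch of each autosome without a mark peak, the transitions of single and combined marks at LSD1 peaks and at sites 2 to 50 kb away, the peaks of at least 4 kb, the densest windows of 1 Mb, and the alternatives with equal covered length, with chromosomes 1 to 22 alone and without clusters.

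Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on simulated data and recovered 100% of planted shared peaks in lists of the size of the DMSO LSD1 (2630), H3K4me1 (85463) and H3K4me2 (71769) lists. The planted peaks were exact copies of listed ones, so this checks the code and not how well displaced peaks are matched. The matched draws were tested on 75993 peaks of the size of the GSK-LSD1 H3K4me2 list. Of 100 simulations without enrichment 3 lay above the 97.5th percentile of the draws, and of 100 simulations with a planted 2-fold enrichment 100 did. Apart from the planted enrichment, nearness depended only on fold enrichment, for which the draws were matched. A smaller enrichment was not simulated.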

Results

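LSD1 (KDM1A) is a histone demethylase that removes methyl groups from mono- and dimethylated lysine 4 of histone H3, the marks H3K4me1 and H3K4me2. H3K4me1 is typical of enhancers, and H3K4me2 of enhancers and promoters. GSK-LSD1 is a small-molecule inhibitor of the enzyme. Primary human epidermal keratinocytes received the inhibitor or DMSO, and LSD1, H3K4me1 and H3K4me2 were mapped with 2 libraries per antibody and treatment. Each of the 6 peak lists pooled its 2 libraries, with 75013348 (DMSO) and 87850490 (GSK-LSD1) tags for LSD1, 93252419 and 104539233 for H3K4me1, and 104211119 and 92823820 for H3K4me2. Differences between treatments are therefore differences between single lists, without a replicate error.

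The first comparison asked where LSD1 was found with and without its inhibitor. The LSD1 list held 2630 peaks with DMSO and 1429 with GSK-LSD1, a ratio of 0.543. Only 131 peaks of each list overlapped a peak of the other, which is 4.98% of the DMSO peaks (95% interval 4.21 to 5.88) and 9.17% of the GSK-LSD1 peaks (7.78 to 10.8). Fewer peaks were listed with the inhibitor on 22 of 22 autosomes, from a ratio of 0.254 on chromosome 13 to 0.944 on chromosome 19. The DMSO peaks that were shared had a median of 5.2 normalised tags (tags per 10000000 sequenced), against 3.6 for those found only with DMSO. In the GSK-LSD1 list the order was the opposite, with a median of 3.41 for shared peaks and 4.1 for those found only with GSK-LSD1. Outside clusters (5 or more peaks, each within 100 kb of the next) the order was that of the DMSO list, with medians of 3.41 for 127 shared peaks and 3.07 for 763 found only with GSK-LSD1.

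**Figure D1:**
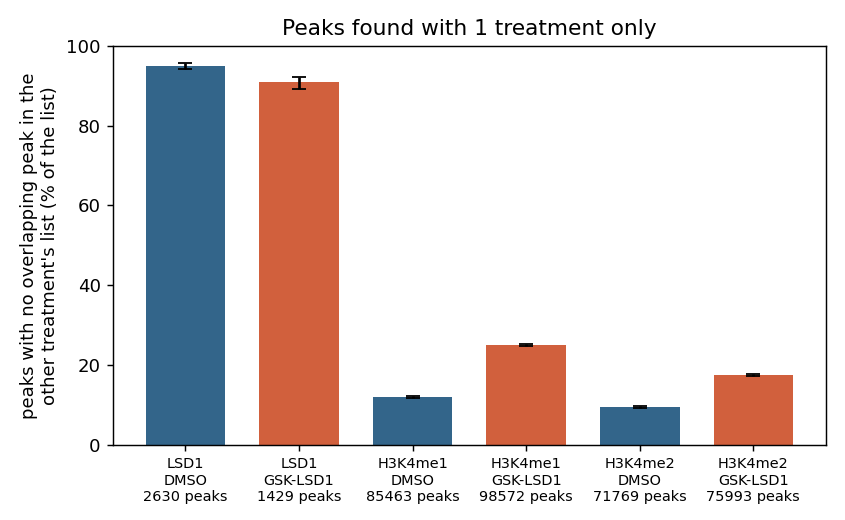
Bars give the percentage of each peak list without an overlapping peak in the other treatment's list, for the 3 antibodies, with 95% Wilson intervals and the number of peaks under each bar. LSD1 peaks were found with 1 treatment only in 2499 of 2630 (DMSO) and 1298 of 1429 (GSK-LSD1) cases, while for the marks the share was higher with GSK-LSD1 (24.9% for H3K4me1 and 17.5% for H3K4me2) than with DMSO (11.9% and 9.45%).

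The strongest LSD1 peak found only with DMSO lay on chromosome 16 at 75520117 to 75520242, with 32 normalised tags and 17.4 times the input. Those on chromosome 17 at 80745470 to 80745595 and on chromosome 9 at 131636836 to 131636961 each had 27.3 normalised tags and 22.2 times the input. Of the 8 strongest peaks of this class, 7 overlapped H3K4me1 and 5 overlapped H3K4me2 in the DMSO lists. All 8 overlapped H3K4me2 in the GSK-LSD1 list. The 3 that did so only in that list were the peak on chromosome 9 and those on chromosome 22 at 41676227 to 41676352 and on chromosome 3 at 142587351 to 142587476. At the site on chromosome 3, H3K4me1 was likewise listed only with GSK-LSD1, whereas at the peak on chromosome 10 at 7299365 to 7299490 it was listed only with DMSO. Each treatment's H3K4me1 list thus overlapped 7 of the 8, though not the same 7. The strongest shared LSD1 peak among the 5 strongest of the DMSO list lay on chromosome 1 at 16840524 to 16840649, where H3K4me2 was listed with both treatments and H3K4me1 with neither. With 26.5 normalised tags it was 4.06 times the input, close to the 4-fold that the caller required. Its 32 input tags were the highest value of the DMSO list.

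The strongest LSD1 peaks of the GSK-LSD1 list lay elsewhere. Its strongest peak, on chromosome 10 at 42380203 to 42380332, had 85.7 normalised tags, 6.03 times the input, and 71 input tags. The next were on chromosome 8 at 43093779 to 43093908 (64.3 normalised tags, 73 input tags) and on chromosome 4 at 49152470 to 49152599 (62.5 normalised tags, 38 input tags). None of the 7 strongest autosomal peaks found only with GSK-LSD1 overlapped a peak of either mark in either treatment, and they ranged from 44.1 to 85.7 normalised tags. In the DMSO class the 8 strongest had 6 to 16 input tags.

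A larger part of the LSD1 peaks lay in clusters along the chromosomes with the inhibitor than without it, though most peaks of both lists lay outside clusters. Clusters held 539 peaks of the GSK-LSD1 list in 37 clusters (37.7%, 35.2 to 40.3), against 45 peaks of the DMSO list in 8 clusters (1.71%, 1.28 to 2.28). The autosomal clusters with the most peaks were on chromosome 7 at 61251276 to 61780921 (29 peaks), chromosome 19 at 27749215 to 27941461 (26 peaks) and chromosome 5 at 46268985 to 46405585 (23 peaks). Each of these lay inside the longest stretch of its chromosome without a peak of either mark. The largest DMSO cluster, on chromosome 6 at 26026638 to 26322910, had 8 peaks. The longest stretch of each autosome without a peak of either mark held 27.8% of the autosomal GSK-LSD1 peaks (25.5 to 30.3) and 0.731% of the DMSO peaks (0.468 to 1.14). Among clustered GSK-LSD1 peaks, 0% overlapped H3K4me1 (0 to 0.708) and 1.48% overlapped H3K4me2 (0.754 to 2.90) in the GSK-LSD1 lists. Outside clusters the shares were 41.2% (38.0 to 44.5) and 43.7% (40.5 to 47.0). Clustered peaks had a median of 5 input tags and unclustered ones a median of 3. The approximate efficiency of the immunoprecipitation was 0.12% with DMSO and 0.09% with GSK-LSD1 per the file headers, so few tags lay in peaks in either list.

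**Figure D2:**
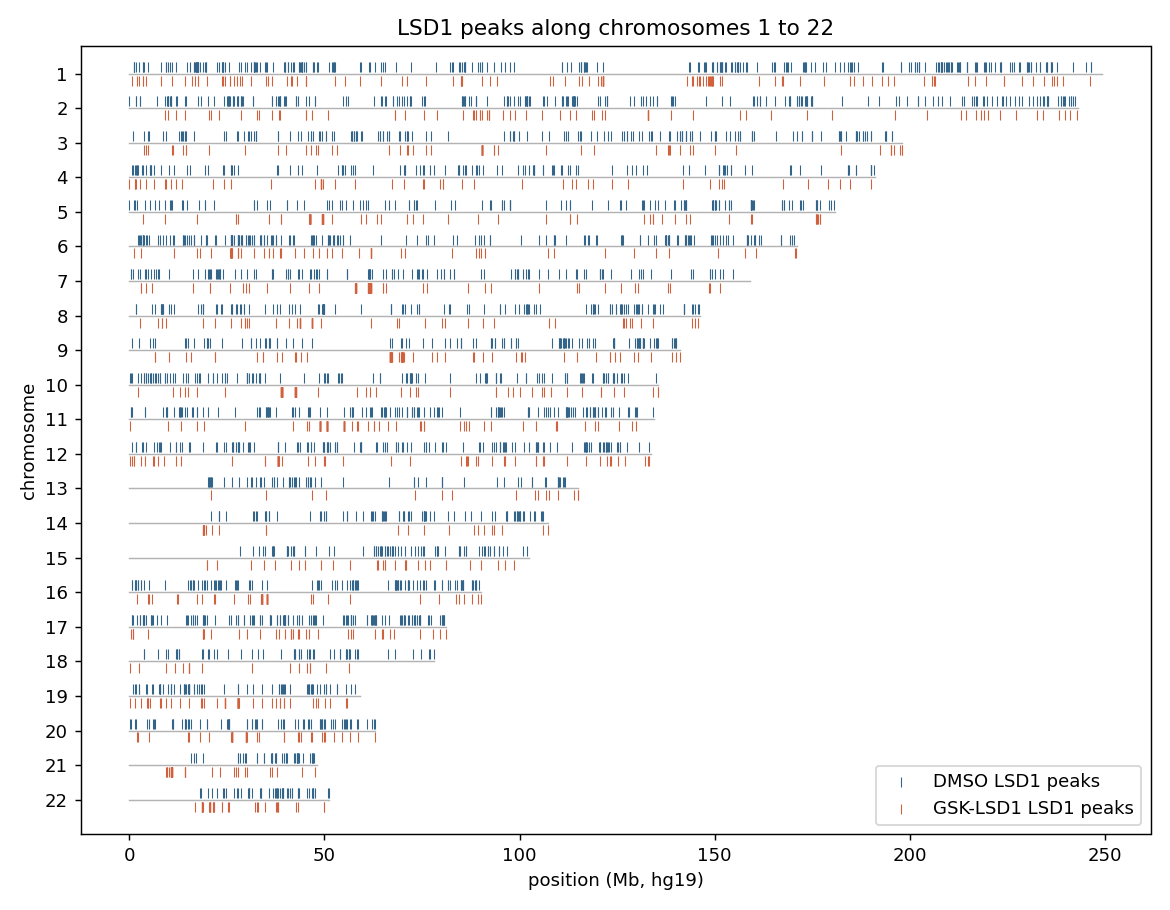
Ticks mark LSD1 peaks along chromosomes 1 to 22 (position in Mb, hg19), with DMSO peaks above each line and GSK-LSD1 peaks below it; a line ends at the last peak of any list. DMSO peaks are spread over the chromosomes, while 37.7% of all GSK-LSD1 peaks lie in clusters, such as that of 29 peaks at 61251276 to 61780921 on chromosome 7. That cluster lies inside the longest stretch of chromosome 7 without a peak of either mark.

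The second comparison asked how H3K4me1 differed when its demethylase was inhibited. H3K4me1 peaks were more numerous and covered more sequence with the inhibitor, with 98572 peaks over 122 Mb against 85463 peaks over 101 Mb with DMSO. The excess was 15.3% in number and 20.5% in length. All 22 autosomes had more peaks with GSK-LSD1, with ratios from 1.12 on chromosome 18 to 1.22 on chromosome 19. Peaks found only with GSK-LSD1 numbered 24583, or 24.9% of the list (24.7 to 25.2), and those found only with DMSO numbered 10166, or 11.9% (11.7 to 12.1).

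Peaks found with 1 treatment only were narrower than shared ones, at a slightly lower fold enrichment. Their median fold was 2.63 in both lists, against 2.71 (DMSO) and 2.81 (GSK-LSD1) for shared peaks. Their median width was 446 bp with GSK-LSD1 and 402 bp with DMSO, against 1084 and 938 bp for shared peaks. Broad H3K4me1 domains of at least 4 kb numbered 2518 with DMSO and 3551 with GSK-LSD1. Of the 3551 domains, 2 had no overlapping peak in the DMSO list, and the others overlapped at least 1 DMSO peak. The strongest peak found only with GSK-LSD1, on chromosome 7 at 151269838 to 151270503, was 4.65-fold over background, and H3K4me2 was listed there with GSK-LSD1 alone as well. The next strongest were on chromosome 14 at 105780129 to 105780428 (4.39-fold) and chromosome 15 at 40812134 to 40812353 (4.36-fold). H3K4me2 was listed at 6 of the 8 strongest of this class with GSK-LSD1 and at 3 of them with DMSO. The strongest peak found only with DMSO was on chromosome 4 at 92542456 to 92542695 (4.27-fold), where H3K4me2 was also listed with DMSO alone. H3K4me2 was present at 7 of the 8 strongest of that class with DMSO and at 6 of them with GSK-LSD1. The weakest GSK-LSD1 peaks were also left out until both lists covered the same length. Then 19.997% of the remaining GSK-LSD1 peaks and 31.9% of the DMSO peaks had no partner, which turns the direction. Leaving out GSK-LSD1 peaks alone removes partners of DMSO peaks by construction, so this turn cannot be read as a result about the mark. Among peaks with a −log10 q of at least 5, which numbered 1866 with GSK-LSD1 and 700 with DMSO, 1.66% and 0.714% had no partner in the other list as deposited.

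For H3K4me2, the other mark that LSD1 removes, the list again was longer with the inhibitor. It held 75993 peaks over 108 Mb with GSK-LSD1 and 71769 peaks over 93.0 Mb with DMSO, an excess of 5.89% in number and 16.5% in length. More peaks were listed with GSK-LSD1 on all 22 autosomes, with ratios from 1.03 on chromosome 12 to 1.12 on chromosome 20. The median peak was 1016 bp wide with GSK-LSD1 and 937 bp with DMSO. Found only with GSK-LSD1 were 13298 peaks (17.5%, 17.2 to 17.8), and found only with DMSO were 6780 (9.45%, 9.24 to 9.66).

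H3K4me2 domains of at least 4 kb numbered 2392 with DMSO and 3473 with GSK-LSD1, and 0 of them were without an overlapping peak in the other list. Domains of at least 8 kb numbered 220 and 365. The strongest peak found only with GSK-LSD1 lay on chromosome 17 at 1545979 to 1546379 (5.46-fold over background), followed by chromosome 20 at 34744630 to 34745206 (5.18-fold) and at 48806704 to 48806948 (5.13-fold). H3K4me1 was listed with GSK-LSD1 at 5 of the 8 strongest of this class, and with DMSO at 0 of the 8. The strongest found only with DMSO lay on chromosome 12 at 25589029 to 25589408 (4.64-fold), where H3K4me1 was also listed with DMSO alone. All 5 strongest H3K4me2 peaks of either list were shared, led by chromosome 5 at 50258952 to 50259708 with DMSO (8.16-fold) and by chromosome 5 at 134879709 to 134880378 with GSK-LSD1 (7.46-fold). With equal covered length the direction turned, at 9.55% of GSK-LSD1 peaks and 26.7% of DMSO peaks without a partner. Here too only GSK-LSD1 peaks were left out, which by construction removes partners of DMSO peaks. At a −log10 q of at least 5 (25841 peaks with GSK-LSD1 and 21249 with DMSO) the shares were 0.654% and 0.0941%.

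Most LSD1 sites of the DMSO cells lay in chromatin that carried the enzyme's substrates. Of the 2630 DMSO LSD1 peaks, 1979 overlapped an H3K4me1 peak (75.2%, 73.6 to 76.9) and 1878 an H3K4me2 peak (71.4%, 69.6 to 73.1) of the DMSO lists. Circular shifts gave means of 3.97% and 3.57%, and 0 of 1000 shifts reached the observed share of either mark. Both marks were present at 1611 sites (61.3%), H3K4me1 alone at 368 (13.99%), H3K4me2 alone at 267 (10.2%) and neither at 384 (14.6%). The share was lower for the LSD1 peaks of the GSK-LSD1 list, at 25.7% for H3K4me1 and 27.8% for H3K4me2 of that treatment, against 4.47% and 3.92% in the shifts. LSD1 peaks shared by both lists were intermediate, at 56.5% and 58.0% in the DMSO lists. Against MACS2 peaks with a −log10 q of at least 5 alone, 1.75% of the DMSO LSD1 peaks overlapped H3K4me1 and 22.4% overlapped H3K4me2.

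The marks at the sites of LSD1 in DMSO cells were then compared between treatments, since these are the regions at which LSD1 was found without the inhibitor. H3K4me2 was more often present there with the inhibitor, at 2262 of the 2630 sites (86.0%, 84.6 to 87.3) against 1878 with DMSO. It was listed only with GSK-LSD1 at 435 sites and only with DMSO at 51, a ratio of 8.53 (6.39 to 11.4). Of the 752 sites without H3K4me2 in DMSO cells, 57.8% (54.3 to 61.3) had a peak with the inhibitor. With both H3K4me2 lists at equal covered length that share was 35.9% (32.6 to 39.4). Of all sites, 72.8% then carried H3K4me2 with GSK-LSD1, against 71.4% with DMSO. Within 1 kb, 82.0% of the DMSO LSD1 peaks had an H3K4me2 peak of the DMSO list, so some of the 752 sites lay beside an existing peak. Only 204 H3K4me2 peaks found only with GSK-LSD1 overlapped a DMSO LSD1 peak, fewer than the 435 gained sites. Unless many of these peaks covered more than 1 LSD1 peak, part of the gained sites therefore lay in peaks shared between treatments. H3K4me1 was listed at 2112 sites (80.3%, 78.7 to 81.8) against 1979, with 262 sites only with GSK-LSD1 and 129 only with DMSO, a ratio of 2.03 (1.65 to 2.51). Here 115 H3K4me1 peaks found only with GSK-LSD1 overlapped a DMSO LSD1 peak.

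Of the 368 sites that carried H3K4me1 without H3K4me2 in DMSO cells, 282 (76.6%, 72.0 to 80.7) carried both marks with the inhibitor. The same count made the other way round gave 32 of 174 sites (18.4%, 13.3 to 24.8) with H3K4me1 alone under the inhibitor and both marks with DMSO. At positions 20 kb away the shares were 41.4% (35.0 to 48.2) and 9.36% (6.26 to 13.8), an asymmetry in the same direction. At equal covered length they were 45.1% (40.1 to 50.2) and 42.8% (38.2 to 47.5) at the LSD1 peaks, and 23.8% (18.6 to 30.0) and 24.4% (19.5 to 30.1) at 20 kb. Of the 1611 sites with both marks, 1469 (91.2%, 89.7 to 92.5) had both again. Sites with both marks numbered 1938 with GSK-LSD1, and sites with neither went from 384 to 194. At positions 20 kb to either side of the LSD1 peaks the ratio of gained to lost sites was 3.32 (2.31 to 4.76) for H3K4me2 and 2.96 (2.19 to 4.02) for H3K4me1. At 2 kb it was 4.20 (3.18 to 5.54) for H3K4me2 and 3.64 (2.93 to 4.51) for H3K4me1. The ratio at the peaks was thus above that at 2 and 20 kb for H3K4me2, beyond the counting intervals, and for H3K4me1 it was below that at 2 kb. This ratio depends on how many sites already carried the mark. Of sites without H3K4me1 in DMSO cells, 40.2% gained it at the peaks, 8.99% at 2 kb and 3.45% at 20 kb. Of sites with it, 6.52%, 10.4% and 10.2% lost it. For H3K4me2 the gains were 57.8%, 5.72% and 2.60%, and the losses 2.72%, 7.80% and 8.98%. With equal covered length the ratio at LSD1 peaks was 1.16 (0.973 to 1.38) for H3K4me2 and 0.961 (0.799 to 1.16) for H3K4me1, and at 20 kb it was 0.920 (0.681 to 1.24) and 1.02 (0.789 to 1.31). At 2 kb, beside the peaks, it stayed at 1.99 (1.57 to 2.52) and 2.06 (1.70 to 2.48). With the same number of peaks in both lists it was 4.86 (3.83 to 6.17) for H3K4me2 at LSD1 peaks and 2.36 (1.68 to 3.32) at 20 kb.

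**Figure D3:**
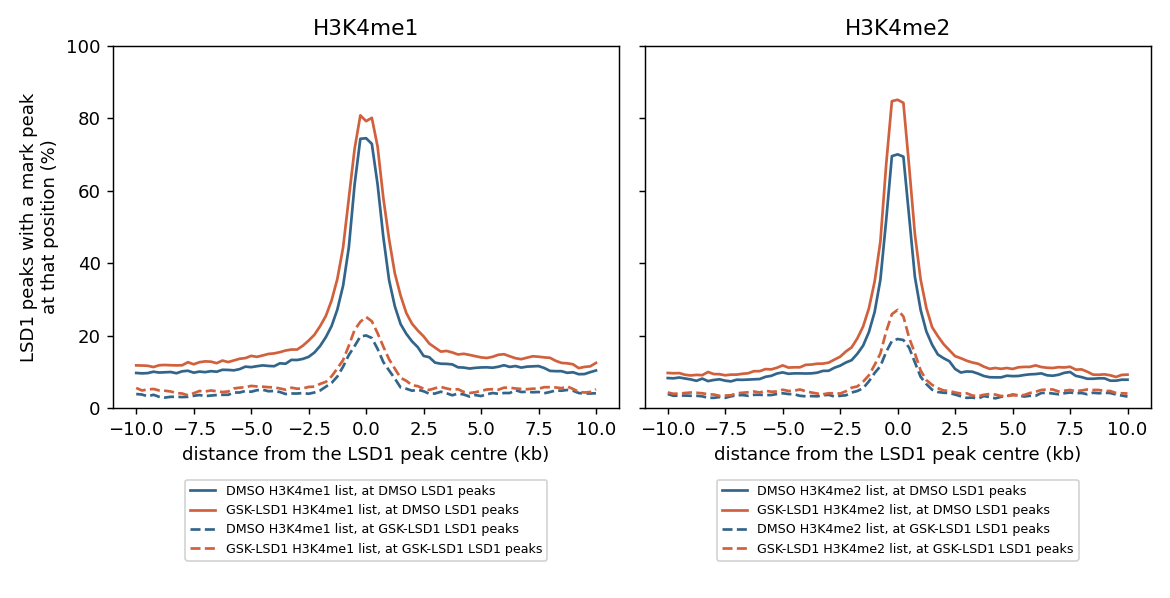
Lines give the percentage of LSD1 peaks that have an H3K4me1 (left) or H3K4me2 (right) peak at each distance from their centre, in kb, for DMSO LSD1 peaks (solid) and GSK-LSD1 LSD1 peaks (dashed) and for the mark lists of DMSO (blue) and GSK-LSD1 (orange). At the centre of DMSO LSD1 peaks H3K4me2 covered 70.1% with DMSO and 85.1% with GSK-LSD1, and H3K4me1 74.5% and 79.2%.

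Seen from the marks, H3K4me2 peaks found only with the inhibitor lay near LSD1 more often than comparable peaks did. Of the 13298 such peaks, 261 (1.96%, 1.74 to 2.21) lay within 1 kb of a DMSO LSD1 peak. Draws matched on width and fold enrichment averaged 1.35% (central 95% of draws 1.196 to 1.52), which is a 1.45-fold excess, and 0 of 10000 draws were as high. Of the 6780 H3K4me2 peaks found only with DMSO, 18 (0.265%, 0.168 to 0.419) lay as close, below the 1.48% of their own matched draws. For H3K4me1, 194 of the 24583 peaks found only with GSK-LSD1 (0.789%, 0.686 to 0.908) lay within 1 kb of an LSD1 peak, 0.904 times the 0.873% of matched draws (central 95% of draws 0.777 to 0.968). Counting direct overlap with an LSD1 peak in place of 1 kb turned that direction, at 0.468% (0.390 to 0.561) against 0.391% in draws (0.325 to 0.464), with 196 of 10000 draws as high. The H3K4me1 peaks found only with DMSO lay there in 40 of 10166 cases (0.393%, 0.289 to 0.535), below the 1.08% of their own matched draws (central 95% of draws 0.905 to 1.26). Without matching, draws held more strong and wide peaks, and the H3K4me2 ratio was 0.625 and the H3K4me1 ratio 0.310. At a −log10 q of at least 5 the H3K4me2 ratio was 2.21, from 6 of 169 peaks, and 487 of 10000 draws were as high.

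The last comparison asked whether both marks differed at the same regions. Among 71199 regions with both marks, 3365 were found only with GSK-LSD1 for both, 2.97 times the 1131 of independent lists. Regions found only with DMSO for both marks numbered 1063, or 5.09 times the 209 of independent lists. Opposite patterns were at or below that level, with 484 regions against 506 for H3K4me1 only with GSK-LSD1 and H3K4me2 only with DMSO, and 286 against 467 for the reverse. Of the H3K4me2 peaks, 84.7% overlapped H3K4me1 with DMSO (84.4 to 84.9) and 89.1% with GSK-LSD1 (88.9 to 89.4). The reciprocal share was slightly lower with the inhibitor: 73.6% of H3K4me1 peaks overlapped H3K4me2 with DMSO (73.3 to 73.9) and 72.7% with GSK-LSD1 (72.4 to 72.9). Both marks were called against the same inputs, so part of the excess may come from those shared controls. At a −log10 q of at least 5, 3 regions were found only with GSK-LSD1 for both marks against 0.0482 for independent lists, a ratio of 62.2 from very few regions.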

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

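Of the tests in this part, those of the tag depth of the marks and inputs, of the strongest DMSO peaks, of the immunoprecipitation efficiency, of lists with equal covered length and of input tags in clusters used comparisons chosen after the result was seen.

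The input column of the LSD1 lists, which the shares of peaks between treatments did not use, held a signal of its own. In the GSK-LSD1 list 135 of 1429 peaks (9.45%, 8.04 to 11.1) had 10 or more input tags, against 38 of 2630 (1.44%, 1.05 to 1.98) in the DMSO list. The highest values were 73 and 32 input tags.

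Of the LSD1 peaks of the GSK-LSD1 list 37.7% lay in clusters, and 9.17% of the list was shared with DMSO. A small loss of tags that took peaks just under the caller's tag threshold is unlikely to be the whole account. Of the 10% of DMSO peaks with the most tags, only 12.5% (9.08 to 17.1) were found with GSK-LSD1. The tags of the GSK-LSD1 libraries at these sites were not analysed here, so the tag threshold is not excluded. The threshold over input stays open, since a peak with many tags can lie close to it. That filter removed 13705 of 16905 putative peaks with DMSO and 6755 of 9303 with GSK-LSD1. The filter over the surrounding sequence, which removed 570 with DMSO and 1119 with GSK-LSD1, stays open as well. A candidate explanation for the clusters is a pile-up of reads where the input is also high, as at repeats that an assembly holds in too few copies: the median of input tags was 1.67 times as high in clusters as outside. The LSD1 signal was higher there too, with medians of 7.29 against 3.07 normalised tags and 7.13 against 6.77 times the input, while 10 or more input tags were found at 17.8% of clustered and 4.38% of unclustered peaks, so a pile-up stays open for part or all of the clusters. Less LSD1 on chromatin under the inhibitor stays open beside a lower yield of the immunoprecipitation, since the header's efficiency of 0.09% with GSK-LSD1 bears on both alike.

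More sequence was called for both marks with GSK-LSD1. The H3K4me2 immunoprecipitates were not sequenced more deeply with GSK-LSD1, since their tags after filtering were 0.891 times those of DMSO. For H3K4me1 deeper sequencing of the immunoprecipitates stays open as a cause, since that ratio was 1.12. A difference between the inputs stays open for both marks, with a ratio of input tags of 1.03. The inputs were the smaller data sets, to which the immunoprecipitates were scaled. The tags of the immunoprecipitates alone therefore do not settle the depth, and the ratio of 0.891 does not exclude it as a cause for H3K4me2. A biological gain of the marks under the inhibitor may also contribute, and no value here separates it from a difference in library quality.

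H3K4me2 peaks appeared at DMSO LSD1 peaks with GSK-LSD1. Width and fold enrichment alone do not account for the position of the H3K4me2 peaks found only with GSK-LSD1. Of these, 1.96% lay near LSD1, above all 10000 matched draws, though at a −log10 q of at least 5 there were 487 draws as high. These draws do not cover the whole pattern. Only 204 such peaks overlapped a DMSO LSD1 peak, against 435 sites with a gain, and gains inside peaks shared with DMSO were not tested. Wider calling of H3K4me2 throughout stays a candidate explanation for the excess of gains. With equal covered length the ratio of gains to losses was 1.16, with an interval that overlaps that of sites 20 kb away. Only GSK-LSD1 peaks were left out for this, which by construction removes gains and adds losses, so the ratio cannot separate wider calling from a broad gain. At the 131 LSD1 peaks of both lists it was 3.13 (1.44 to 6.79), and 1.00 (0.231 to 4.33) at 20 kb. At equal covered length the ratio 2 kb from the DMSO LSD1 peaks stayed at 1.99 (1.57 to 2.52), above the sites 20 kb away. The trimmed GSK-LSD1 list covered its 93.0 Mb with 55657 peaks, against 71769 with DMSO, so its peaks were wider on average. The value at 2 kb therefore cannot separate a gain from wider peaks. A gain of H3K4me2 where the demethylase was bound is a biological hypothesis that remains open beside wider calling.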

How the results depend on the processing

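The tests with equal covered length, with chromosomes 1 to 22 alone, without clusters, and with the same number of peaks at LSD1 sites were chosen after the results were seen. Of 72 values recomputed for 13 results, 25 stayed within the counting interval of the original and 47 did not, of which 2 crossed a ratio of 1 from a value whose interval excluded it (H3K4me1 gains over losses with equal covered length and the H3K4me2 fold without matching). No paired analysis was possible because each peak list analysed here pools both libraries of its group, so the library numbers that recur across groups could not be used; leaving out a replicate was ruled out likewise. Reads of single libraries were not analysed here. Alternatives for gene lists were not run. Keeping all sequences moved nothing, since no peak lay elsewhere. What a different depth would change was not tested. Except where construction is named, the cause was not tested.

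Percentages without a partner are given for DMSO, then GSK-LSD1. For LSD1, GSK-LSD1 alone moved with an overlap of 50% of the shorter peak (92.2%) and without clusters (86.0%). The strongest 50% of each list gave 93.1% and 93.0%, and the same number of peaks 93.4% and 93.4%. An overlap of 50% gave 14.6% and 27.4% for H3K4me1 and 10.9% and 18.8% for H3K4me2. Partners within 1 kb gave 10.3% and 22.7%, and 8.71% and 16.6%. A −log10 q of at least 5 gave 0.714% and 1.66%, and 0.0941% and 0.654%. The same number of peaks gave 20.9% and 22.8%, and 12.7% and 16.0%. Equal covered length gave 31.9% and 19.997%, and 26.7% and 9.55%; leaving out weak GSK-LSD1 peaks by construction removes partners of DMSO peaks, so the direction turned. H3K4me1 with GSK-LSD1 was 24.2% with peaks within 1 kb merged and 24.7% on chromosomes 1 to 22.

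LSD1 peaks at H3K4me1 and H3K4me2 were 86.9% and 82.0% within 1 kb, 1.75% and 22.4% at a −log10 q of at least 5, 25.7% and 27.8% in the GSK-LSD1 lists, and 56.5% and 58.0% for LSD1 peaks of both lists. Gains over losses at LSD1 peaks were 0.961 (H3K4me1) and 1.16 (H3K4me2) with equal covered length, and 1.52 and 4.86 with the same number of peaks. Folds over draws were 0.310 (H3K4me1) and 0.625 (H3K4me2) without matching, 1.195 (H3K4me1) for direct overlap, 1.27 (H3K4me2) within 5 kb, and 1.14 and 2.21 at a −log10 q of at least 5, where the excess of shared differences was 62.2.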

Other observations

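The windows, the LSD1 clusters and the transitions at GSK-LSD1 sites in this part were chosen after the data were seen, and no test of an explanation was added to those above.

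Windows of 1 Mb were ranked by the excess in number of peaks found with 1 treatment only, which favours windows rich in peaks. In the whole lists, 24.9% of H3K4me1 and 17.5% of H3K4me2 peaks with GSK-LSD1 were found only there. For H3K4me1, the window on chromosome 1 from 17000001 to 18000000 had 32 peaks found only with GSK-LSD1, of 109, against 2 found only with DMSO. Chromosome 19 held 3 of the 5 windows with the largest excess, from 3000001 to 4000000 (33 against 3), from 18000001 to 19000000 (32 against 2) and from 38000001 to 39000000 (29 against 1). These held 83, 120 and 85 GSK-LSD1 peaks. For H3K4me2 the largest excess was on chromosome 3 from 195000001 to 196000000, with 20 of 50 GSK-LSD1 peaks against 0. Windows with the opposite pattern recurred in both marks. On chromosome 2 from 40000001 to 41000000, 16 H3K4me1 and 13 H3K4me2 peaks were found only with DMSO, against 4 and 5 only with GSK-LSD1. On chromosome 12 from 90000001 to 91000000 the values were 13 and 12 only with DMSO against 6 and 4 only with GSK-LSD1.

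The 8 clusters of LSD1 peaks in DMSO cells all spanned at least 1 H3K4me1 peak of that treatment, whereas the 10 largest autosomal clusters of the GSK-LSD1 list spanned 0. The other clusters among the 37 of the GSK-LSD1 list were not examined for this. The DMSO clusters were 54.5 to 296 kb long, and how often stretches of that length hold an H3K4me1 peak was not computed. After the cluster on chromosome 6 the DMSO clusters lay on chromosome 2 at 113799662 to 114087875 and chromosome 5 at 159208890 to 159410057, with 6 peaks each. The others, with 5 peaks each, included chromosome 17 at 39675878 to 39942407, chromosome 10 at 72015629 to 72237683 and chromosome 19 at 15254988 to 15426148.

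Both marks differed in the same direction at the LSD1 peaks of the GSK-LSD1 list, which were called against the same inputs as the GSK-LSD1 marks. H3K4me2 was listed only with GSK-LSD1 at 121 of the 1429 peaks and only with DMSO at 8, a ratio of 15.1 (7.50 to 30.5), against 3.00 (1.49 to 6.05) at positions 20 kb away. With equal covered length the ratio was 2.78 (1.86 to 4.15), against 0.857 (0.461 to 1.59) at 20 kb. H3K4me1 was listed only with GSK-LSD1 at 85 peaks and only with DMSO at 13, a ratio of 6.54 (3.68 to 11.6), against 2.56 (1.45 to 4.53) at 20 kb. With equal covered length it was 2.56 (1.64 to 3.97), against 1.15 (0.686 to 1.94) at 20 kb. Of the 90 such peaks with H3K4me1 alone in DMSO cells, 72 (80.0%, 70.6 to 87.0) carried both marks with the inhibitor, and of the 40 with H3K4me1 alone under the inhibitor, 5 (12.5%, 5.46 to 26.1) carried both with DMSO. At 20 kb these shares were 39.1% (26.4 to 53.5) and 16.0% (8.34 to 28.5). At equal covered length they were 60.0% (49.7 to 69.5) and 31.1% (21.7 to 42.3) at the peaks, and 23.9% (13.9 to 37.9) and 26.3% (16.6 to 39.0) at 20 kb.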
